A study of Canis lupus familiaris with 109 samples.

How the data were processed

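Whole-blood DNA of domestic dogs was treated with bisulfite and prepared for sequencing by the Roche SeqCap Epi capture protocol, per the labels' protocols. The submitters' processing notes name Trim Galore, Bismark 0.14.3, Bowtie2 2.1.0 and the CanFam3.1 build, without saying in which step each was used. The deposited values are methylation fractions per cytosine position and library, without read counts or coverage, so the depth and the precision it gives are unknown and no coverage minimum was applied here.

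Of the 3 deposited tables, the main table holds fractions for 95 libraries at 304191 positions and has no empty cell. Most of its values have 2 decimals, and 0.781% of cells have more. These are treated as filled in, a step for which no method is given in the sources used here. Their share had a median of 0.0404% per library and reached 22.4% in the library coded L1_A7. The repeat table holds fractions for 7 libraries at 1812277 positions, with 2.68% of cells empty, and covers 89% of the positions of the main table. The table mapped to human probes holds fractions for 95 libraries at 54469 probes, on a scale that differs from the main table, and it was described within itself.

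The labels give each sample's age, and life stages were set from it before the data were examined. Library codes in the rows of the tables (95 in the main table and 7 in the repeat table) match no title or description. Rows were not tied to samples by order or by their values, and all 102 rows were left without a group. For this reason the planned limma tests of age, life stage and sex, the age prediction, the gene-level tests and gene lists, the rule for named genes, and the exact sign-flip test of the repeat captures were not run. The gene annotation at hand is on another assembly than the tables and was not used here. All tests and settings described below, other than the correlation, the absolute difference and the mean difference between repeat libraries and 2 alternatives of them, were chosen after the data were seen.

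A position's level is the median of its fractions over the 95 libraries. Positions under 0.1 were called unmethylated and positions over 0.8 methylated. Density is the number of listed positions within 100 bp on either side. Regions are runs of at least 10 positions with gaps of up to 100 bp, and a region's level is the mean over its positions in each library. Coordinates are the first coordinate the table lists, and whether it counts from 0 or from 1 was not settled, so that positions carry an uncertainty of 1 bp. Strand was taken from positions listed in consecutive pairs in the repeat table, which gave 24854 CpGs with both strands in the main table. Variant-like positions had at least 8 libraries under 0.12, at least 8 over 0.88 and at least 8 between 0.3 and 0.7, with at most 12 in the gaps. They were left out of the comparison of repeat libraries, as were filled-in cells. A value counted as 1.0 within a tolerance of 1e-06.

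Correlations across libraries were tested with 100000 permutations, two-sided, for Pearson's r and Spearman's rho, and the 3 relations computed were adjusted together by the Benjamini-Hochberg method. Relations were recomputed within each of the 10 code prefixes (L1 to L9 and SCE), and the relation between dense and sparse positions also with the mean of each prefix or of each second element of the code taken out (10000 permutations within them). On simulated tables of 20 libraries at 13940 mostly unmethylated positions, binomial reads gave 31222 cells of 0.01, 12153 of 0.02 and none of 1.0. With a small unconverted share that rose from library to library, there were 40460 cells of 0.01, 47114 of 0.02 and none of 1.0. The share was drawn for each read and position independently, not for whole molecules. The absence of 1.0 in these 2 simulated tables therefore followed in effect from their settings. Reads drawn as in the first table, with 0.01 written as 1.0, gave 31397 cells of 1.0 and none of 0.01, which that setting fixes in advance. On a simulated table with 200 variant positions among 20000 others, 100% were found, 0 others were called, and 6 of 6 repeat libraries were matched. The simulation had fewer libraries and a lower minimum per class than the data, and all its variants were common. Its other positions had the same level in every library apart from read noise, so that 0 calls among them followed from the setting. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.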

Results

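DNA methylation was measured in whole blood of domestic dogs by targeted bisulfite sequencing, in which bisulfite treatment lets unmethylated cytosines be read as thymine while methylated cytosines stay cytosine, and a capture step selects the regions sequenced. The labels list 109 samples, whose titles name 103 dogs, whereas the series' design text counts 104. Of these, 94 samples fall into 4 life stages by the age on the label. The 13 juvenile samples (under 0.5 years) had a median age of 0.227 years, the 6 adolescent samples (0.5 to under 2 years) 1.57 years, the 35 mature samples (2 to under 7 years) 4.83 years and the 40 senior samples (7 years or more) 9.87 years. Sex was recorded for 61 of the 94. The labels further list 6 repeat captures, 1 sample used only with these repeats, and 8 samples of low coverage.

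The study asks how the blood methylome of dogs changes with age and how this compares with humans. The rows of the tables carry library codes that match none of the labels, so no library was tied to an age, a sex or a life stage, and no comparison of ages, stages or sexes is made here. The values below are therefore ranges and medians over 95 libraries of unassigned samples, 1 more than the 94 samples of the life stages. Read depth is unknown, since the tables give fractions without counts, and no interval is given for single values. No annotation on the genome build of the tables was used here, so regions are named by position on CanFam3.1. The named regions were chosen after their values were seen.

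The captured positions fell into a methylated and an unmethylated class. Of 304191 cytosine positions on the 38 autosomes, 153855 (50.6%) had a median methylation fraction under 0.1 over the 95 libraries, 99651 (32.8%) had a median over 0.8, and 50685 (16.7%) lay between. The class followed the local density of listed positions. Among the 73373 positions with 1 to 3 listed positions within 100 bp, itself included, 14.2% were unmethylated and 58.5% were methylated. Among the 9888 positions with 32 to 88 listed positions, 91.3% were unmethylated and 0.324% were methylated. By chromosome, the unmethylated share was highest on chromosome 32, at 64.5% of 3269 positions, and lowest on chromosome 38, at 36.3% of 2323 positions. The median local density was 9 positions on chromosome 32 and 5 on chromosome 38.

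**Figure D1:**
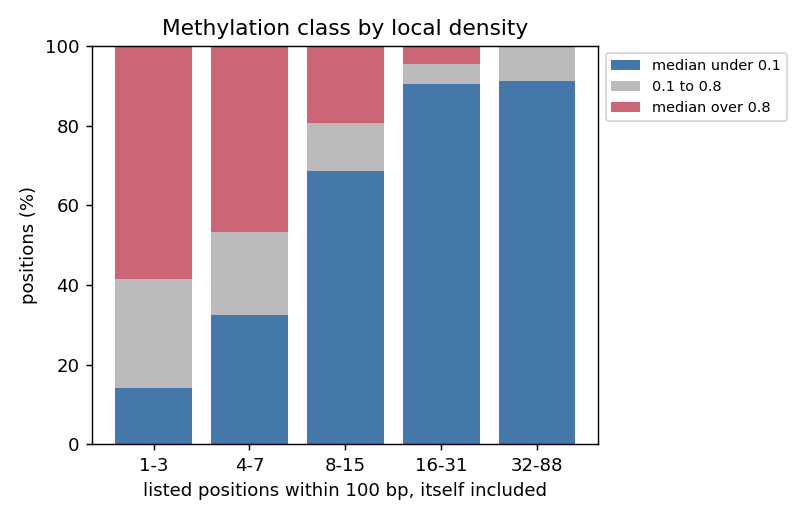
Share of positions (percent, vertical axis) with a median methylation fraction under 0.1, from 0.1 to 0.8, and over 0.8 in 95 libraries, by the number of listed positions within 100 bp (horizontal axis). The unmethylated share was 14.2% in the sparsest class and 91.3% in the densest.

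Dense clusters of positions were mostly unmethylated in blood. Runs of at least 10 positions with gaps of up to 100 bp gave 7274 regions with a median length of 184 bp. For region levels, values of exactly 1.0 at positions with a median under 0.05 were set to 0.01, a setting described with the library means. Of the 7274 regions, 5184 (71.3%) had a median level under 0.1 and 1118 (15.4%) a median level over 0.8. The longest unmethylated region spanned 1165 bp on chromosome 12 from 434282 to 435446. It held 92 positions and had a median level of 0.00217, with a highest library of 0.00565. A region of 104 positions on chromosome 16 from 9418336 to 9419281 had a median level of 0.00183 and a highest library of 0.00462. A region of 54 positions on chromosome 12 from 2663559 to 2664548 lay higher, at a median of 0.0548 with libraries from 0.0343 to 0.093.

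A small set of regions had intermediate median levels. In 40 regions the median level lay between 0.4 and 0.6 and at least 80% of the positions had medians between 0.3 and 0.7, and in 5 of these the standard deviation across libraries was under 0.06. A pair of neighbouring regions on chromosome 14 was among the 5. The first ran from 20121504 to 20122024 with 68 positions, a median level of 0.429 and libraries from 0.346 to 0.579. The second ran from 20122267 to 20122402 with 10 positions, a median of 0.461 and libraries from 0.333 to 0.582. The region with the smallest standard deviation was on chromosome 2 from 35986576 to 35986780, at a median of 0.446, although its libraries, from 0.313 to 0.689, spanned a wider range than those of the chromosome 14 regions. The other two were on chromosome 20 from 39037627 to 39037790 (median 0.572) and on chromosome 32 from 24889680 to 24889928 (median 0.443).

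Other regions ranged widely between libraries. The most variable was on chromosome 28 from 3528117 to 3528456. Its 49 positions had a median level of 0.19, with libraries from 0 to 0.92, 50 libraries under 0.2 and 13 over 0.5. A second variable region of 15 positions lay 14242 bp away, from 3513875 to 3514117, with a median of 0.169 and libraries from 0.0267 to 0.805. On chromosome 26 from 5330973 to 5331232, 16 positions had a median of 0.459 and libraries from 0.121 to 0.929. This region's level correlated at 0.903 with the first principal component of the libraries, which differed by the second element of the library code. On chromosome 5 from 78455022 to 78455134, 14 positions had a median of 0.547 and libraries from 0.29 to 0.936. On chromosome 7 from 38896094 to 38896187, 19 positions had a median of 0.519 and libraries from 0.04 to 0.931. The median correlation between positions across the 95 libraries was 0.725 in the first chromosome 28 region and 0.853 in the chromosome 26 region. Among the 8 most variable regions it ran from 0.668 to 0.874. Regions were ranked by the spread of their mean level, which is large only where positions move together. High correlations therefore follow in part from the choice, and they were not compared with those of other regions. None of the 8 most variable regions held a position with the pattern of a sequence variant, as defined for the repeat libraries. Such positions are rare, at 269 of 304191, so that their absence from 8 short regions says little. The rule also misses rarer variants and variants outside the listed positions, and an effect of genotype on these regions was not tested.

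Measured fractions at neighbouring positions varied together over short distances. For positions with median fractions from 0.2 to 0.8, the median correlation across libraries was 0.573 for pairs 2 to 10 bp apart (7011 pairs). It was 0.412 at 51 to 100 bp, 0.219 at 201 to 500 bp and 0.0936 at 1001 to 5000 bp. For the 2864 pairs 1 bp apart, which are the opposite strands of one CpG and are read from different molecules, the median was 0.244. The other pairs were not separated by strand. Nearby positions on one strand can be read in the same molecules, and shared sampling noise can then raise their correlation. How much of the values at short distances comes from this was not tested. Within a library and across CpGs, which are not independent replicates, fractions of the opposite strands correlated with a median r of 0.784 over the 95 libraries, from 0.573 to 0.918, at 2909 intermediate CpGs.

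The mean fraction per library had a median of 0.385, from 0.375 to 0.451. The highest library, coded L4_A7, had 38.8% of its cells over 0.8, against a median of 31.8%. Among the 142292 positions with a median under 0.05, this library held 22444 values of exactly 1.0, or 15.8%, against a median of 614 per library. No cell of the main table or of the repeat table held 0.01, whereas 415967 cells of the main table held 0.02. With the 1.0 at these positions set to 0.01, a setting chosen after seeing the data, the library means had a median of 0.382 and ranged from 0.369 to 0.389. The number of positions with a standard deviation over 0.1 across libraries was 145884 as deposited and 46120 after the change. Of these, 105512 and 5748 were positions with a median under 0.1.

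**Figure D2:**
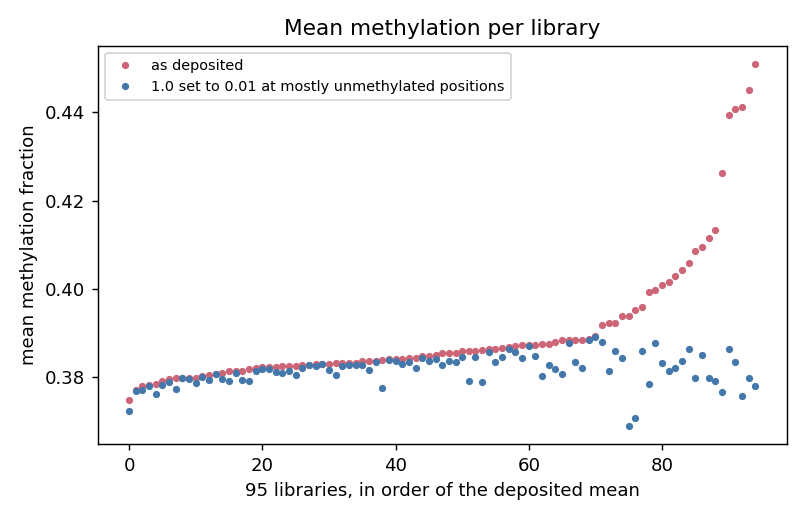
Mean methylation fraction (vertical axis) of each of 95 libraries, in order of the deposited mean (horizontal axis), as deposited and with 1.0 set to 0.01 at positions with a median under 0.05. The deposited means reached 0.451 and the changed means 0.389.

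The labels describe a repeat of the capture for 6 dogs, which asks how closely a measurement repeats. In the repeat table, 6 libraries have codes starting with CHYB6, each with a number that also occurs in a code starting with SCE_CF_Pilot. As the codes match no label, the planned test over dogs was not run, and the values are given per shared number. Shared numbers were checked at 269 autosomal positions at which libraries fell near 0, near 0.5 and near 1, as a sequence variant at the cytosine gives, of which 235 were in both tables. For each of the 6 CHYB6 libraries, the closest of all other libraries outside the CHYB6 set was the Pilot library of the same number. Its correlation across these positions was 0.964, 0.858, 0.972, 0.946, 0.966 and 0.965 for numbers 1, 5, 6, 7, 8 and 10. The next closest library reached 0.687 for number 1 and at most 0.422 for the other numbers.

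**Figure D3:**
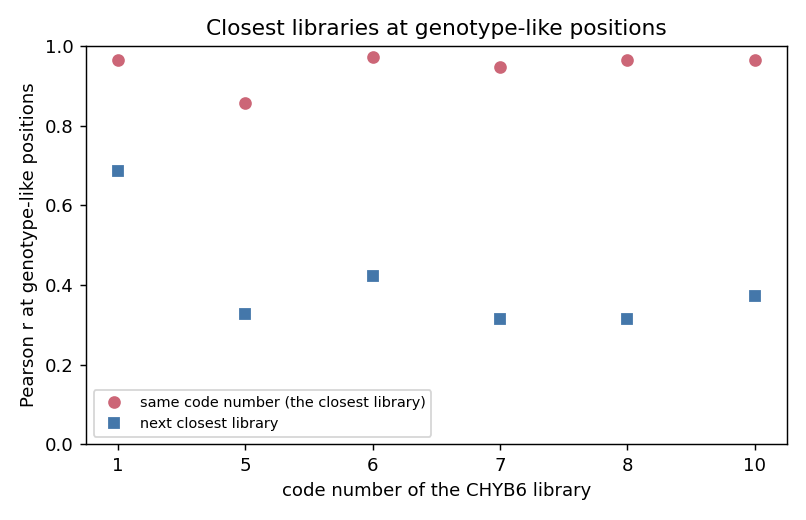
Pearson correlation across variant-like positions (vertical axis) of each CHYB6 library with the library of the same code number and with the next closest library, by code number (horizontal axis). The same-number values lay between 0.858 and 0.972, and the next closest reached 0.687.

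Over the other shared positions, libraries of the same number correlated with a median r of 0.963 across positions, from 0.927 to 0.98. The median absolute difference of a fraction was 0.01 or 0.02 in each pair over all of these positions, of which many lie near 0, and from 0.06 to 0.1 at positions with a fraction between 0.1 and 0.9 in the Pilot library. Libraries of other numbers had median r from 0.93 to 0.966. For numbers 5 and 10, the same-number r of 0.947 and 0.927 lay below the median r with other libraries, 0.948 and 0.930, and below the highest, 0.956 and 0.936. For the other 4 numbers it lay above the highest r with another library. With 1.0 set to 0.01 at positions with a median under 0.05, the same-number r ranged from 0.977 to 0.987. It was then highest for numbers 5 and 10, at 0.9873 and 0.9866. Their Pilot libraries also had the highest shares of 1.0 at these positions, 2.1% and 2.21%. The r with other libraries is not given under this setting. The mean fraction was higher in the CHYB6 library in 5 of 6 pairs, with differences from -0.0017 to 0.00573 and a median of 0.00286. With 1.0 set to 0.01 it was higher in 6 of 6 pairs, with a median difference of 0.000766, and the sign turned for number 5, from -0.0017 to 0.000556. At positions with a fraction between 0.1 and 0.9 in the Pilot library the median difference was 0.0125, but selecting on one library of a pair can itself shift the difference. With 1.0 set to 0.01 and positions selected on the mean of both libraries, it was 0.00264, higher in 5 of 6 pairs.

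The table of dog positions mapped to human array probes held 54327 probes named cg and 142 named ch in the same 95 library codes. On the human array these names stand for CpG and non-CpG probes. Its values ran from 0.0836 to 0.97, and library means lay between 0.484 and 0.486. In each library between 21.9% and 34.9% of cells sat at that library's lowest value. At the 18352 probes with a median under 0.15, the share of values over 0.9 ran from 0% to 9.65% per library, with a median of 0.245%, and was highest in the library coded L4_A7, which also had the highest mean in the main table. The ch probes were mostly high, with 73.9% at a median over 0.8 and 0.704% under 0.2. Whether the dog positions given to ch probes are CpGs was not checked, and the values are rescaled. These shares therefore give no level of non-CpG methylation in dogs. Of the cg probes, 34.8% had a median over 0.8 and 38.6% under 0.2.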

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

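No result met the rules for a closer look that rest on groups, since no library was tied to a group. A pattern in the values is weighed here, with tests chosen after it was seen. Some libraries held many values of exactly 1.0 at positions with a median under 0.05, from 8 in the library coded L7_A15 to 22444 in L4_A7. Incomplete bisulfite conversion would leave neighbouring unmethylated cytosines of the same molecules unconverted, so that most are read as methylated too. However, 19.3% of same-strand neighbours within 12 bp of such a 1.0 were over 0.5, above the 8.17% given by each library's own rate. Methylation of the CpG itself in most molecules would show on both strands. Of partner-strand values beside a 1.0, 10.9% were over 0.5, against 8.42% at the library's own rate and 93.2% at intermediate positions. Such methylation would also recur in a repeat library. In the CHYB6 libraries 12.8% to 25.2% of the 1.0 cells of the same-number Pilot library were over 0.5, against 0.154% to 3.11% of all such positions. Most of the 1.0 cells did not recur, but a part did, and not only between libraries of the same number. At the 1.0 cells of other libraries the median share was 4.27% to 13.3%, below the same-number share for every number. Of 88 other libraries, 5, 12, 2, 0, 1 and 6 reached the same-number share for numbers 1, 5, 6, 7, 8 and 10. What raised the same-number share was not tested. Over all such positions the CHYB6 cells over 0.5 were mostly 1.0 as well, since 0.131% to 3.08% of them held 1.0 there. How many of the recurring cells held 1.0 was not counted. If 1% was written as 1.0, positions near 1% would recur as 1.0 too. Without that count, the recurring part cannot tell such writing from methylation or a property of the position. A candidate explanation is that 1% was written as 1.0 when percentages were turned into fractions. No cell with 2 decimals held 0.01, while 369145 cells at these positions held 0.02 and 255707 held 1.0. All 941 cells within 0.0001 of 0.01 had more than 2 decimals.

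Under this explanation, libraries with more 0.02 should have more 1.0, and the counts correlated across the 95 libraries with r = 0.614 (permutation p = 1e-05, the smallest possible, adjusted 1.5e-05) and rho = 0.95 (p = 1e-05). Without the 2 libraries farthest from the median, r was 0.613, and within the 10 code prefixes r ranged from 0.354 to 0.991. The count of 1.0 was related to the level of positions with a median over 0.9 with r = -0.366 (permutation p = 0.002, adjusted 0.002) and rho = -0.322 (p = 0.0014), and r = -0.35 without the 2 farthest libraries. Within prefixes this r ranged from -0.788 to 0.0453. What raised the neighbour share above the library's own rate was not tested. A difference between libraries in read depth stays untested, since no read counts are given. A difference between dogs in age or sex also stays untested, since the codes are not tied to labels. The first principal component of the deposited values held 8.84% of the variance and correlated with the count of 1.0 at an absolute r of 0.982, and after 1.0 was set to 0.01 its share was 7.73% and that correlation 0.0941.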

How the results depend on the processing

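The alternatives here were chosen after seeing the data, other than the restriction of the repeat comparison to fractions between 0.1 and 0.9 and to positions with a value in every repeat library. Depth is unknown, so its effect could not be examined. With 1.0 set to 0.01 at mostly unmethylated positions, the highest library mean moved from 0.451 to 0.389, the count of variable positions from 145884 to 46120, and the median r of repeat libraries from 0.963 to 0.985, which follows from the change itself. The median and the lowest library mean moved by less than the spread between libraries. With the mean over libraries in place of the median, the unmethylated share was 48.8% in place of 50.6%. It was 54.3% with a boundary of 0.2, and the methylated share was 36.5% with a boundary of 0.7 in place of 32.8%, as wider classes give. Leaving out filled-in values gave 50.6% and 32.8%. At CpGs between 0.3 and 0.7, the median r between strands was 0.641 in place of 0.784. A narrower range of levels by itself lowers such an r, and no other cause was tested. At fractions between 0.1 and 0.9, the median r of repeat libraries was 0.925 and their median mean difference 0.0125 in place of 0.00286, with positions selected on one library of each pair. Selected on the mean of both, with 1.0 set to 0.01, these were 0.902 and 0.00264. With 1.0 set to 0.01 alone, the difference was 0.000766, and for number 5 its sign turned. Positions with a value in every repeat library gave 0.963 and 0.00286. Of 40 intermediate regions, 5 had a standard deviation under 0.06 and 0 under 0.04. Libraries of the same number were compared by values only, with no test over pairs, because the table rows are tied to no sample. The alternatives fixed before the data were examined for age, life stage, sex, age prediction and gene results were not run for the same reason.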

Other observations

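The tests in this part were chosen after the patterns were seen, while what 2 of them would show, those on code prefixes and on the second element of the code, was written before their values were computed. Across libraries, dense positions of low methylation and sparse positions of high methylation moved in opposite directions. With 1.0 set to 0.01 at mostly unmethylated positions, the mean over 4779 positions with at least 16 listed positions within 100 bp and a mean fraction of 0.05 to 0.3 ranged from 0.0879 to 0.162. The mean over 28627 positions with fewer than 4 listed positions and a mean fraction of 0.5 to 0.9 ranged from 0.727 to 0.808. Their correlation over 95 libraries was r = -0.503 (permutation p = 1e-05, the smallest possible, adjusted 1.5e-05) and rho = -0.488 (p = 1e-05), and r = -0.433 without the 2 farthest libraries.

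If 1% written as 1.0 were the whole cause, the relation would end with every 1.0 at the dense positions set to 0.01. It did not end, as r was then -0.478 (permutation p = 1e-05). With values as deposited r was -0.506 at the same positions, and -0.252 when positions were chosen anew from the deposited means. Batches marked by the code prefix would leave no relation within prefixes, but r was below 0 in 10 of 10 prefixes, from -0.813 to -0.134 with a median of -0.536, and was -0.511 with each prefix's mean taken out (permutation p = 0.0001, the smallest that 10000 permutations give). Single prefixes are small: the permutation p was under 0.05 in 3 of 10, and without the 2 farthest libraries r was 0.0447 in L4 and 0.0603 in L8. Batches marked by the second element of the code (A1 to A27) would leave none once each element's mean is taken out, but r was then -0.396 (permutation p = 0.0022 from 10000 permutations within elements). No biological explanation was tested, as the codes are not tied to labels, so the source of the relation stays open.

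The leading axis of the changed values followed a set of regions. Of the 7274 regions, 182 correlated with the axis with r over 0.5 and 237 with r under -0.5, a description only, since the axis was made from the same positions. The highest was on chromosome 9 from 3827585 to 3827749, with r = 0.905 and libraries from 0.0127 to 0.712, followed by the variable region on chromosome 26 from 5330973 to 5331232, with r = 0.903. The lowest was on chromosome 9 from 24868760 to 24869054, with r = -0.881 and libraries from 0.298 to 0.957. Scores on the axis differed by the second element of the code. Over the 24 elements in the 84 libraries with codes from L1 to L9, the median score ran from -0.107 (A11, 3 libraries) to 0.247 (A4, 6 libraries). The libraries of A4 lay between -0.0862 and 0.301 and those of A1, 4 in number, between 0.204 and 0.255. The second element took up 71.8% of the variance of the scores, where 27.7% is expected by chance, and the code prefix 3.72%, where 9.64% is expected.

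At the 269 variant-like positions, the 4465 pairs of libraries in the main table had a median correlation of 0.124. In 15 pairs it was over 0.45, and the highest was 0.646, between L3_A1 and L4_A1, below the 0.858 to 0.972 of libraries that share a code number. The next were L2_A3 with L2_A20 at 0.612 and L9_A19 with L1_A13 at 0.6. The CHYB6 library of number 5 had the lowest same-number value, 0.858.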
